A study of Homo sapiens with 9 samples.

How the data were processed

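RNA of OE-19 cells, a HER2-positive line established from an esophageal adenocarcinoma, was measured on 9 Illumina HumanHT-12 BeadChip arrays, a 1-colour platform on which each probe is carried by many beads. The arrays fall into 3 groups of 3 per the labels: the parental line, called S, and 2 lines resistant to trastuzumab emtansine (T-DM1), called TR and TCR. Per the labels' protocols, TR and TCR were kept under constant T-DM1 and then grown without it for 72 hours before RNA was taken, while S was never exposed. How TCR was selected, and so what sets it apart from TR, is not given in the labels used here. The 3 arrays of a resistant line come from that line alone and do not replicate resistance. Other differences between a line and S cannot be told apart from it. Total RNA was taken with Trizol, cleaned on columns with DNase treatment, checked on a Bioanalyzer and labelled as biotinylated cRNA, per the labels' protocols. The labels call the samples triplicates and do not say whether they came from separate cultures, so p-values measure the spread between these samples, which may be technical.

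The authors deposited, per the file headers, a table with a probe intensity and a detection p-value for each of 47323 probes on each array. GenomeStudio produced it per the submitters' processing notes, and its version and settings are not given in the sources used here. The deposited intensity values are linear and ran from 88.7 to 25866.3, with a different median on each array, so they were taken as neither background-subtracted nor normalized. The deposited detection p-value of a probe moves in steps of 1 in 770, the resolution that 770 negative control beads would give. The columns were checked against each other: the 9 detection columns fell with their own intensity column with at most 3 steps the other way, against at least 16465 steps with another array's column. A separate deposited table holds processed intensity values of the same arrays. Its columns have the same sorted values to within 0.7 intensity units, each has a median of 136.5, and each has a rank correlation of at least 0.999998 with its own raw column, so its scale is linear, its direction is that of the raw intensity and it carries quantile normalization without background subtraction. The exact settings of that normalization stay unknown. After log2 it served as an alternative.

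The raw intensities were background-corrected with limma's normexp method, with the background estimated from the detection p-values and an offset of 16, then quantile normalized and put on the log2 scale. A probe was kept if its detection p was under 0.05 on all 3 arrays of at least 1 group, which left 18676 probes. Probe names came from a table of the platform's annotation. In it 30113 probes had 1 gene symbol, 8 had several and 17202 had none there, and these last are unnamed here. Entrez identifiers of 30074 named probes (99.9%) matched a RefSeq gene table of assembly GRCh38.p14, and 0 symbols needed an update. That table served for names, for which genes neighbour each other and for the span of each gene, and its coordinates are used for nothing else. Of the kept probes, 4348 had no single symbol and stayed out of the gene comparisons. Each of 10757 genes was represented by its kept probe with the highest mean over all arrays. For the 2855 genes with more than 1 kept probe, the other probes are cited for named genes where their sign differs, and for BEX1.

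The comparisons were TR minus S, TCR minus S and TCR minus TR. The 9 arrays were fitted together in limma with a mean for each group (6 residual degrees of freedom, 4.91 prior degrees of freedom from the moderation), and p-values were adjusted by the Benjamini-Hochberg method within a comparison. A gene is called where its adjusted p is under 0.05, and 2-fold counts also ask for a log2 difference of at least 1 in size. All p-values are two-sided. Where the probe used for a gene was not above background (detection p of 0.05 or more) on any array of the dimmer group, the fold is a bound, written "at least". It sets the mean of the brighter group against the mean of, per array, the higher of the lowest signal among detected probes and the probe's own signal. The number of arrays limits the precision of every value. Probes can pick up close relatives of their gene, so KRT16 and KRT16P2, CST1, the HLA genes, IFITM2, REG1A and the GSTM genes are uncertain.

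Genes named in the text follow a rule set in advance. It takes 19 fixed genes of HER2, transport, prostaglandin, tubulin and adhesion biology, the 10 largest rises and 10 largest falls against S in each line, the 5 largest each way between the lines, and the 10 genes each way with the largest change shared by both lines. The ranked genes had to be called with the arrays of the 2 groups not overlapping, which chance alone gives for 10% of genes; those ranked for both lines only had to be called in both. For a list that is described, up to 4 members with the smallest adjusted p may be named. There were 29 gene lists with 875 different genes, 55 of which have no named probe here. They cover HER family receptors and ligands, genes around ERBB2, ABC drug transporters, tubulins, microtubule-associated proteins, the prostaglandin pathway, integrins, cadherins and cell junctions, extracellular matrix, mesenchymal transition, lysosome, endocytosis, mitosis, DNA replication, interferon response, antigen presentation, inflammatory cytokines and NF-kB targets, NRF2 and xenobiotic metabolism, apoptosis, p53 targets, MAPK and PI3K output, cholesterol biosynthesis, hypoxia and glycolysis, the unfolded protein response, gastric and intestinal epithelium, squamous epithelium, and markers of fibroblasts and of leukocytes, and 1 further list is not reported here. The lists on HER2, ABC transporters, tubulins, microtubules, prostaglandins, integrins, junctions and matrix were fixed with knowledge of published work on these lines, so their direction is not independent evidence. Lists with at least 5 measured genes were tested with limma's camera, which asks whether a list moves against all other genes, with a preset correlation between genes of 0.01. The same test with an estimated correlation and limma's fry, which asks whether a list's genes move on balance one way, stand beside it. For each list the number of genes called is given over all genes and adjusted over the list alone.

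TR and TCR share the S arrays, so their changes correlate without any effect. Unchanged groups were simulated 100 times against shared controls with the fitted spread of each gene, and the simulated values stand beside the observed ones. Neighbouring genes were scanned in windows of 20 tested genes along the RefSeq order, against 1000 permuted orders. Each fit was tested on simulated data with 10757 genes, 200 of them changed. In the simulated TR minus S, TCR minus S and TCR minus TR, 35.8%, 35.8% and 41.8% of genes changed 1.5-fold were recovered, 92.5%, 91.0% and 97.0% of those changed 2-fold, and 100% of those changed 4-fold, with 10, 9 and 8 false calls. In the same tests the shifted list was called and 0 of the unchanged lists among 28 were. The simulated genes varied independently of each other. The tests therefore cannot show how often camera calls an unchanged list whose genes are correlated. A planted run of 60 neighbours among 10750 placed genes was found in full for TR minus S, and 0 runs were found where none was planted.

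The alternatives were no background correction, an offset of 50, cyclic loess, median scaling, the deposited normalized values, detection p under 0.01, no filter on dim probes, the mean of a gene's probes, fits on 6 arrays, a replicate block, eBayes with trend and robust settings, array weights, an adjusted p under 0.01, and each array left out in turn. The design, the gene lists, the rule for named genes and these alternatives were chosen before the data were examined. The work used R 4.3.3, limma 3.58.1, version 1.17.8 of data.table, Python 3.11.15 and matplotlib 3.10.9.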

Results

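Gene expression was compared between the parental line OE-19 (S) and 2 derived lines that are resistant to T-DM1 per the labels (TR and TCR), with 3 arrays per line. T-DM1 joins trastuzumab, an antibody against HER2, to a maytansinoid that blocks microtubule assembly. The resistant lines had been off the drug for 72 hours, so each comparison is between lines and none is between treated and untreated cells. Between 18351 (TCR replicate 3) and 20866 (S replicate 1) of 47323 probes were detected on an array. The first principal component carried 50.4% of the variance and separated the S arrays from the 6 resistant arrays, and the second carried 15.8%. S replicate 1 correlated with the other S arrays at r = 0.975 and 0.978, which correlated with each other at 0.993. Within TR the lowest correlation was 0.991, and within TCR 0.989.

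The comparison of TR with S asked which genes differ in a T-DM1-resistant line. Genes that handle prostaglandins stood among the largest rises. PTGS2, the inducible cyclooxygenase of prostaglandin synthesis, rose from a log2 intensity of 8.08 ± 0.65 to 11.81 ± 0.19 (SD, n = 3 arrays each), a log2 difference of 3.73 ± 0.29 (SE) with a limma adjusted p of 1.15e-05. PTGER2, a receptor for prostaglandin E2 detected on 1 of 3 S arrays, rose 14.4-fold (log2 3.85 ± 0.16, SE) and SLCO2A1, a prostaglandin transporter, rose 10.3-fold (log2 3.36 ± 0.13, SE). CST1, a secreted inhibitor of cysteine proteases, rose 35.2-fold with a log2 difference of 5.14 ± 0.35 (SE). SLC46A3, a lysosomal membrane transporter of maytansinoid catabolites, fell from 8.61 ± 0.15 to 5.37 ± 0.08 (SD, n = 3 arrays each), with an adjusted p of 2.99e-07.

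Among the other large rises in TR, S100A9, a calcium-binding protein of the calprotectin complex, was at least 6.17-fold higher, since S arrays did not detect it. PGC, the precursor of the gastric protease pepsin C, rose by 3.07 on the log2 scale, the ferroxidase HEPH by 2.97, the pseudogene KRT16P2 by 2.57 and the growth factor carrier FGFBP1 by 2.56. The homeodomain protein HOPX, whose probe was below background on all S arrays, was at least 3.83-fold higher. SGPP2, a phosphatase of sphingosine-1-phosphate, whose probe was below background on all TR arrays, was at least 18.0-fold lower. The probe used for BEX1 fell by 4.69, while its other kept probe differed by -0.98. Also below background in TR were IGFBP2, an insulin-like growth factor carrier, at least 9.65-fold lower, the potassium channel subunit KCNS3, at least 9.35-fold lower, and ANXA13, an annexin of the gut, at least 7.20-fold lower. OLFM4, a marker of intestinal stem cells, was also below background in TR and at least 6.63-fold lower. The glycogen enzyme PGM1 fell by 3.53, the elongation factor TCEA3, detected on 1 of 3 TR arrays, fell by 3.51, and TPPP3, a relative of a tubulin polymerization factor, fell by 3.24. The adjusted p of the genes in this paragraph was at most 2.4e-05.

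**Figure D1:**
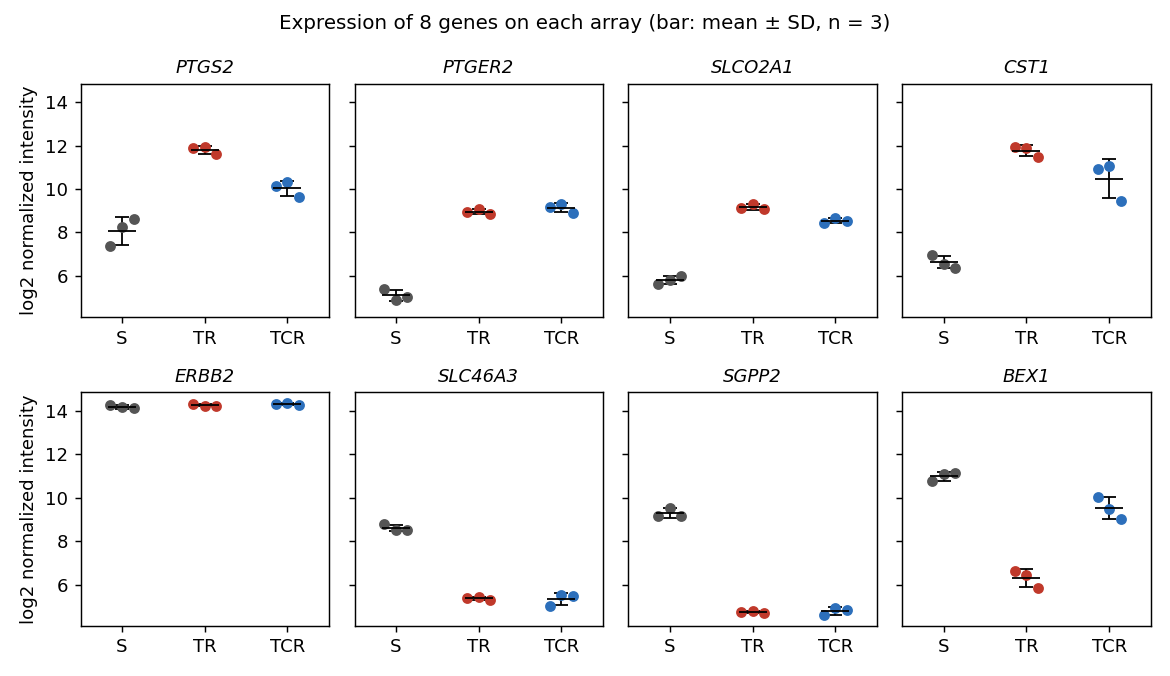
Log2 normalized intensity (y axis) of 8 genes on each array of S, TR and TCR (x axis), 1 dot per array, with bars for the mean ± SD (n = 3). PTGS2, PTGER2, SLCO2A1 and CST1 lie higher on every resistant array than on every S array, SLC46A3, SGPP2 and BEX1 lie lower, and ERBB2 lies near 14 on all 9 arrays.

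ERBB2, the gene of the antibody's target, stood at a log2 intensity of 14.26 ± 0.05 in TR and 14.18 ± 0.08 in S (SD, n = 3 arrays each), a difference of 0.07 with an adjusted p of 0.653, and its other kept probe differed by -0.02. ERBB3 differed by -0.07 (adjusted p = 0.739, other probe 0.19), and EGFR rose by 0.73 (adjusted p = 0.00509). Of 10 genes of HER receptors and ligands, 3 rose and 1 fell, the same number as adjusted over the list alone, and the list was not called (adjusted p = 0.695).  Of 18 genes around ERBB2, 1 rose (IKZF3, a lymphoid transcription factor, by 1.01) and 1 fell by 1.11 (PPP1R1B, a phosphatase inhibitor whose probe was detected on 2 of 3 TR arrays), again with the same number adjusted over the list alone (list adjusted p = 0.794). Of the drug efflux genes, ABCC2 rose by 0.50 (adjusted p = 0.0164), ABCG2 differed by -0.03 (adjusted p = 0.927), ABCB1 was not detected on any array, and ABCC1 was not analysed here. Of 10 ABC transporters 2 rose, also adjusted over the list alone, with the lipid transporter ABCA3 up by 1.78 (list adjusted p = 0.645). TUBB3, a beta-tubulin isotype of neurons, rose by 1.58 ± 0.13 (SE, adjusted p = 1.87e-05), and TUBB6, whose probe was below background in TR, was at least 1.53-fold lower. Of 14 tubulins 3 rose and 2 fell, also adjusted over the list alone (list adjusted p = 0.794), with a median of -0.03 against a mean of 0.12. Without genes of the shifted neighbourhoods described below, 2 of 12 tubulins rose and 1 fell. The change of a single tubulin may therefore belong to a shift of its neighbourhood. Of 26 microtubule-associated proteins 1 rose and 2 fell, also adjusted over the list alone (list adjusted p = 0.640), with the microtubule-destabilizing STMN1 down by 1.14. Because these lists were drawn up with knowledge of published work on these lines, they are not independent evidence of direction.

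Of 20 prostaglandin genes, 5 rose and 3 fell in TR, and 6 rose and 4 fell adjusted over the list alone. Camera did not call the list (adjusted p = 0.479), while fry gave an adjusted p of 0.000259. The prostaglandin E2 receptor PTGER4 rose by 0.81 (adjusted p = 0.0217). PTGS1, the constitutive cyclooxygenase, differed by 0.13 (adjusted p = 0.461), the terminal synthase PTGES by -0.15 (adjusted p = 0.621) and the degrading enzyme HPGD by -0.48 (adjusted p = 0.0772).

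Of 36 genes of cadherins and cell junctions, 15 rose and 0 fell in TR, and 20 rose and 1 fell adjusted over the list alone (list adjusted p = 6.72e-06, and adjusted p = 0.177 with an estimated correlation). At an unadjusted p under 0.05 limma gave 21 and 1. The desmosomal cadherin DSC2 rose by 1.44, the tight junction protein CLDN3 by 1.62, the intestinal cadherin CDH17 by 1.10 and CDH1, epithelial cadherin, by 0.76 ± 0.12 (SE). Of 15 integrins 6 rose and 2 fell, and 9 rose and 2 fell adjusted over the list alone (list adjusted p = 0.0104, and adjusted p = 0.152 with an estimated correlation). ITGB5 rose by 0.95, its partner ITGAV by 0.91 and ITGA6, a laminin receptor subunit, by 1.19. Of 26 matrix genes 14 rose and 1 fell, and 15 rose and 2 fell adjusted over the list alone (list adjusted p = 0.000257, and adjusted p = 0.152 with an estimated correlation), with thrombospondin THBS1 up by 1.79, the matricellular CCN1 up by 1.10 and the laminin chain LAMA1 down by 1.18. Of 7 mesenchymal transition genes 0 rose and 1 fell, and adjusted over the list alone 0 did either way (list adjusted p = 0.794), with 0 up and 1 down at an unadjusted p under 0.05. VIM, a mesenchymal filament, differed by 0.16 (adjusted p = 0.690), and CAV1, the caveolar coat protein, by 0.11 (adjusted p = 0.684, other probe -0.26). RND3 rose by 0.75 (adjusted p = 0.0317). The integrin, junction and matrix lists share the origin stated above and are not independent evidence.

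The list with the smallest p in TR held inflammatory cytokines and NF-kB targets. Of its 17 genes 10 rose and 0 fell, and 13 rose and 1 fell adjusted over the list alone and at an unadjusted p under 0.05 (list adjusted p = 2.95e-06, and adjusted p = 0.0343 with an estimated correlation). The chemokine CCL20 rose by 2.04, the iron carrier LCN2 by 2.01, CXCL1 by 1.38 and NFKBIA, the feedback inhibitor of NF-kB, by 0.91. Of 11 antigen presentation genes 5 rose and 0 fell, and 5 rose and 1 fell adjusted over the list alone and at an unadjusted p under 0.05 (list adjusted p = 0.0260, and adjusted p = 0.341 with an estimated correlation). B2M, the light chain of HLA class I, rose by 0.78. Of 20 interferon response genes 6 rose and 1 fell, also adjusted over the list alone (list adjusted p = 0.380), among them HERC6 up by 0.96 and ISG15 down by 0.80. Of 41 lysosome genes 13 rose and 1 fell, and 16 rose and 1 fell adjusted over the list alone (list adjusted p = 0.00237, and adjusted p = 0.352 with an estimated correlation). The cholesterol carrier NPC2 rose by 0.80 and the peptidase TPP1 by 0.94, and SLC46A3 was the member that fell. Of 37 endocytosis genes 4 rose and 6 fell, and 4 rose and 7 fell adjusted over the list alone (list adjusted p = 0.881, with a median of 0.05 and a mean of -0.04), with RAB4A, a GTPase of recycling endosomes, down by 1.01.

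Of 11 squamous epithelium genes 5 rose and 0 fell in TR, and 6 rose and 0 fell adjusted over the list alone (list adjusted p = 0.000597, and adjusted p = 0.0868 with an estimated correlation), with the cornified envelope gene SPRR3 up by 2.20, KRT13 up by 1.13 and 7 up and 0 down at an unadjusted p under 0.05. Of 27 gastric and intestinal genes 8 rose and 2 fell, and 11 rose and 2 fell adjusted over the list alone (list adjusted p = 0.0319, and adjusted p = 0.166 with an estimated correlation). CDX2, the intestinal transcription factor, rose by 1.62. Of 19 genes of cholesterol synthesis 7 rose and 1 fell, also adjusted over the list alone (list adjusted p = 0.0208, and adjusted p = 0.338 with an estimated correlation), with the demethylase CYP51A1 up by 0.84 and SC5D up by 1.42. Of 29 genes of DNA replication 0 rose and 7 fell, also adjusted over the list alone (list adjusted p = 0.0123, and adjusted p = 0.353 with an estimated correlation), with 0 up and 11 down at an unadjusted p under 0.05. CCNE1, the cyclin of S phase entry, fell by 0.66.

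The remaining lists were not called in TR. Of 30 mitosis genes 1 rose and 0 fell, and 0 did either way adjusted over the list alone (list adjusted p = 0.479), with 1 up and 3 down at an unadjusted p under 0.05. Of 28 NRF2 and xenobiotic genes 5 rose and 4 fell, and 6 rose and 5 fell adjusted over the list alone (list adjusted p = 0.847), with the cystine transporter SLC7A11 up by 1.46 and ALDH1A1 down by 1.94. Of 26 apoptosis genes 6 rose and 3 fell, and 6 rose and 4 fell adjusted over the list alone (list adjusted p = 0.838), with the survival gene BCL2, whose probe was below background in S, at least 1.47-fold higher and the pro-apoptotic PMAIP1, detected on 2 of 3 S arrays, up by 1.29. Without genes of the shifted neighbourhoods described below, 3 of 23 apoptosis genes rose and 3 fell. The rise of a single apoptosis gene may therefore belong to a shift of its neighbourhood. Of 15 p53 targets 2 rose and 1 fell, also adjusted over the list alone (list adjusted p = 0.695), with GDF15 up by 1.06. Of 27 MAPK and PI3K output genes 8 rose and 2 fell, also adjusted over the list alone (list adjusted p = 0.343), with INPP4B, a lipid phosphatase, up by 1.03 and the immediate early gene EGR1 down by 0.95. Of 25 hypoxia and glycolysis genes 6 rose and 2 fell, and 7 rose and 3 fell adjusted over the list alone (list adjusted p = 0.700), with the glucose transporter SLC2A1 up by 1.25. Of 24 genes of the unfolded protein response 3 rose and 3 fell, also adjusted over the list alone (list adjusted p = 0.965). The median and the mean differed in sign for hypoxia (-0.0034 and 0.11) and for the unfolded protein response (-0.0019 and 0.02, with camera pointing down). Of 6 leukocyte markers 0 passed in either direction, also adjusted over the list alone (list adjusted p = 0.794), with 0 up and 2 down at an unadjusted p under 0.05. Of 15 fibroblast markers 2 were measured and 0 were called in either line, too few for a list test.

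In all, limma called 1250 genes higher and 1070 lower in TR than in S, of which 240 and 188 changed at least 2-fold. Median scaling gave 670 and 1156, and without S replicate 1 the counts were 1249 and 1056, with 10 lists again called. They fell to 777 and 661 without TR replicate 1, to 826 and 667 without TR replicate 2, and to 713 lower genes without TR replicate 3, and antigen presentation, cholesterol synthesis and the gut list each had an adjusted p of 0.0556 without TR replicate 1 (antigen presentation 0.0503 without S replicate 3). The calls of ABCC2 (without TR replicate 1 or 2), PTGER4 (without TR replicate 2 or 3) and RND3 (without S replicate 1 or 2 or any TR array) ended with highest adjusted p of 0.0722, 0.0756 and 0.0935, those of ABCC2 and DNA replication ended under median scaling (adjusted p of 0.123 and 0.0535), and up to 7 lists were called when the same 6 arrays were regrouped across the lines.

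The comparison of TCR with S asked the same question of the other resistant line. PTGER2 rose 16.3-fold, with a log2 difference of 4.03 ± 0.16 (SE, n = 3 arrays per group) and an adjusted p of 1.14e-07. PTGS2 rose from 8.08 ± 0.65 to 10.03 ± 0.35 (SD, n = 3 arrays each), with an adjusted p of 0.000871, and SLCO2A1 rose 6.68-fold. SCNN1A, the alpha subunit of the epithelial sodium channel, fell by 4.38 ± 0.11 on the log2 scale (SE, adjusted p = 4.65e-09). SLC46A3 fell by 3.27 ± 0.15 (SE, adjusted p = 3.33e-07) and was detected on 2 of 3 TCR arrays.

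The other large rises in TCR were CST1 by 3.84, HEPH by 3.03, ALDH1A2, an enzyme that makes retinoic acid, by 2.88, the junction protein CXADR by 2.83, UBTD1 by 2.81, the collagen chaperone FKBP10 by 2.81, the antiproliferative gene BTG3 by 2.59 and the Wnt transcription factor LEF1 by 2.56 on the log2 scale. Genes below background on all TCR arrays included SGPP2, at least 17.04-fold lower, IGFBP2, at least 9.13-fold lower, CYB5R2, a cytochrome b5 reductase, at least 9.10-fold lower, KCNS3, at least 8.85-fold lower, ACTL8, an actin relative, at least 7.78-fold lower, and ANXA13, at least 6.81-fold lower. TCEA3, detected on 1 of 3 TCR arrays, fell by 3.63, and PGM1 fell by 3.53. The adjusted p of the genes in this paragraph was at most 3.31e-05. Of 1826 genes called in TCR, 369 lay in runs of neighbouring genes described below, so their changes may not be separate.

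ERBB2 differed by 0.14 between TCR and S (adjusted p = 0.438) and ERBB3 by -0.10 (adjusted p = 0.649), with -0.02 and 0.25 for their other probes, while EGFR rose by 0.63 (adjusted p = 0.0118). ABCC2 rose by 0.43 (adjusted p = 0.0346), and ABCG2 differed by 0.04 (adjusted p = 0.908). TUBB3 rose by 1.01 (adjusted p = 0.000354), and TUBB6, below background in TCR, was at least 1.45-fold lower (adjusted p = 0.000566). As in TR, the change of a single tubulin may belong to a shift of its neighbourhood. Of 10 HER genes 2 rose and 0 fell, of 10 ABC transporters 3 rose and 0 fell, of 18 genes around ERBB2 1 rose and 2 fell, of 14 tubulins 3 rose and 2 fell, and of 26 microtubule-associated proteins 1 rose and 3 fell. These counts were the same adjusted over the list alone, and the lists had adjusted p of 0.439, 0.350, 0.589, 0.876 and 0.588 in that order. At an unadjusted p under 0.05 the HER genes gave 3 up and 2 down and the ABC transporters 3 up and 0 down. STMN1 fell by 1.23 and MED24, a Mediator subunit, by 0.99. Of 20 prostaglandin genes 4 rose and 2 fell, also adjusted over the list alone (list adjusted p = 0.588, and 0.00189 by fry), with a median of -0.07 against a mean of 0.25. PTGER4 differed by 0.56 (adjusted p = 0.100), PTGS1 by -0.07 (adjusted p = 0.731), PTGES by -0.17 (adjusted p = 0.620) and HPGD by -0.16 (adjusted p = 0.608). The PTGS1 probe was below background on all TCR arrays, so its value does not show stable expression.

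Of 36 junction genes 14 rose and 1 fell in TCR, and 17 rose and 1 fell adjusted over the list alone (list adjusted p = 7.68e-07, and adjusted p = 0.148 with an estimated correlation), with DSC2 up by 1.73, the gastric claudin CLDN18 up by 1.08, CDH17 up by 0.97 and CDH1 up by 0.64. Of 15 integrins 7 rose and 0 fell, and 8 rose and 2 fell adjusted over the list alone and at an unadjusted p under 0.05 (list adjusted p = 0.0118, and adjusted p = 0.134 with an estimated correlation), with ITGAV up by 0.73 and ITGB5 up by 0.61. Of 26 matrix genes 7 rose and 1 fell, and 9 rose and 2 fell adjusted over the list alone (list adjusted p = 0.0342, and adjusted p = 0.347 with an estimated correlation), with THBS1 up by 1.46 and the collagenase MMP1 up by 0.96. These 3 lists are not independent evidence, as stated for TR. Of 7 mesenchymal transition genes 0 rose and 2 fell, and 0 rose and 3 fell adjusted over the list alone (list adjusted p = 0.354, with 1 up and 3 down at an unadjusted p under 0.05), among them S100A4, a motility-linked calcium binder, down by 0.86. VIM differed by 0.58 (adjusted p = 0.159) and CAV1 by 0.01 (adjusted p = 0.980, other probe -0.18). RND3 rose by 0.84 (adjusted p = 0.0234).

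Of 17 inflammatory and NF-kB genes 6 rose and 0 fell in TCR, and 7 rose and 0 fell adjusted over the list alone (list adjusted p = 0.000546, and adjusted p = 0.0675 with an estimated correlation), with CCL20 up by 1.56, CXCL8 up by 1.61 and 10 up and 0 down at an unadjusted p under 0.05. Of 27 gastric and intestinal genes 9 rose and 1 fell, and 11 rose and 2 fell adjusted over the list alone (list adjusted p = 0.000996, and adjusted p = 0.0675 with an estimated correlation). CDX2 rose by 2.12, and OLFM4, detected on 1 of 3 TCR arrays, fell by 2.73. Of 11 squamous genes 4 rose and 0 fell, and 5 rose and 0 fell adjusted over the list alone (list adjusted p = 0.00341, and adjusted p = 0.0989 with an estimated correlation), with KRT13 up by 1.80, SPRR3 up by 2.01 and 6 up and 0 down at an unadjusted p under 0.05. Of 11 antigen presentation genes 5 rose and 0 fell, also adjusted over the list alone (list adjusted p = 0.0266, and adjusted p = 0.347 with an estimated correlation), with HLA-E up by 0.99, B2M up by 0.57 and 6 up and 0 down at an unadjusted p under 0.05.

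Of 30 mitosis genes 0 rose and 2 fell in TCR, and 0 rose and 1 fell adjusted over the list alone (list adjusted p = 0.00808, and adjusted p = 0.513 with an estimated correlation), with PTTG1, the securin of chromosome separation, down by 0.54 and 0 up and 6 down at an unadjusted p under 0.05. Of 29 DNA replication genes 0 rose and 3 fell, also adjusted over the list alone (list adjusted p = 0.00814, and adjusted p = 0.347 with an estimated correlation), with CCNE1 down by 0.57 and 0 up and 10 down at an unadjusted p under 0.05. Of 41 lysosome genes 9 rose and 4 fell, and 11 rose and 4 fell adjusted over the list alone (list adjusted p = 0.106), with TPP1 up by 1.06. Of 37 endocytosis genes 3 rose and 3 fell, and 4 rose and 3 fell adjusted over the list alone (list adjusted p = 0.601), with RAB4A down by 1.05. Of 20 interferon genes 5 rose and 1 fell, and 5 rose and 4 fell adjusted over the list alone (list adjusted p = 0.250), with OASL up by 1.32. Of 26 apoptosis genes 5 rose and 1 fell, and 5 rose and 4 fell adjusted over the list alone (list adjusted p = 0.350), with the pro-apoptotic BIK up by 1.55. Of 28 NRF2 and xenobiotic genes 3 rose and 4 fell, also adjusted over the list alone (list adjusted p = 0.848), with ALDH1A1, detected on 2 of 3 TCR arrays, down by 2.45. Of 27 MAPK and PI3K output genes 4 rose and 1 fell, and 7 rose and 3 fell adjusted over the list alone (list adjusted p = 0.160), with PHLPP1, a phosphatase of AKT detected on 1 of 3 S arrays, up by 1.49.

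Of 19 cholesterol genes 5 rose and 0 fell in TCR, and 6 rose and 1 fell adjusted over the list alone and at an unadjusted p under 0.05 (list adjusted p = 0.122), with TM7SF2, a sterol reductase, up by 0.94. Of 25 hypoxia and glycolysis genes 5 rose and 2 fell, and 6 rose and 3 fell adjusted over the list alone (list adjusted p = 0.838), with the glucose transporter SLC2A3 up by 1.49 and BNIP3 down by 0.92. Of 24 genes of the unfolded protein response 3 rose and 4 fell, and 4 rose and 5 fell adjusted over the list alone (list adjusted p = 0.501), with VLDLR, a lipoprotein receptor, down by 1.22. Of 15 p53 targets 3 rose and 0 fell, also adjusted over the list alone (list adjusted p = 0.350), with 5 up and 1 down at an unadjusted p under 0.05. The median and the mean differed in sign for hypoxia (-0.02 and 0.04), endocytosis (0.13 and -0.0049), tubulins (-0.0041 and 0.02) and leukocyte markers (0.01 and -0.03), and camera pointed up for endocytosis. Of 6 leukocyte markers 0 passed, also adjusted over the list alone (list adjusted p = 0.867), with 0 up and 1 down at an unadjusted p under 0.05.

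**Figure D2:**
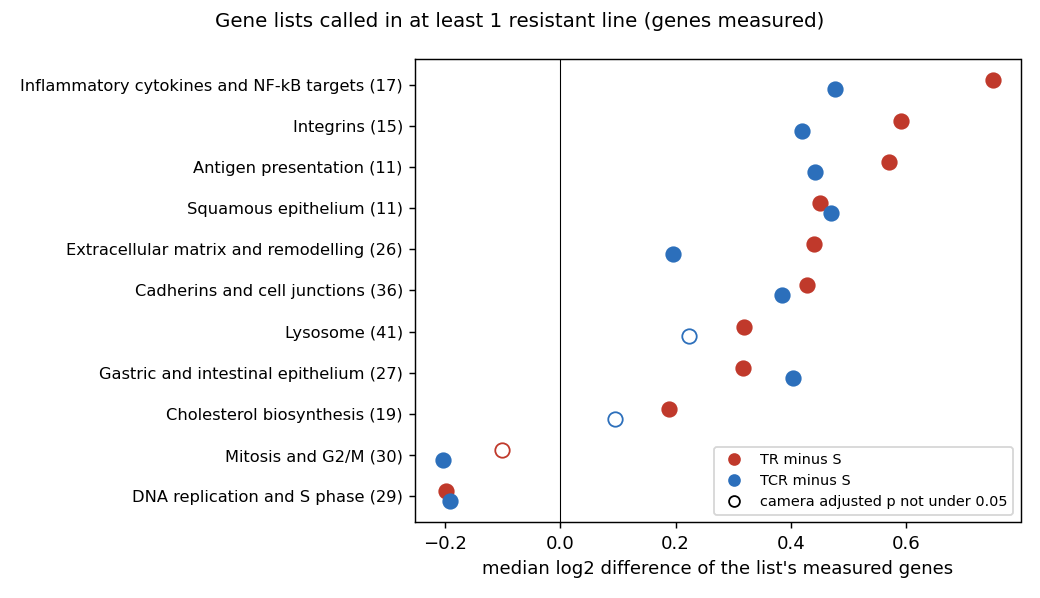
Median log2 difference from S (x axis) of the measured genes of each list called in at least 1 resistant line (y axis, number of genes in brackets), with red for TR, blue for TCR and open circles where the camera adjusted p was not under 0.05. The inflammatory list lies at 0.75 in TR and 0.48 in TCR, and the DNA replication list lies below 0 in both, at -0.20 and -0.19.

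In all, limma called 916 genes higher and 910 lower in TCR than in S, of which 189 and 224 changed at least 2-fold, and the counts were 1003 and 978 without S replicate 1, when p53 targets and lysosome were called too (adjusted p of 0.0270 and 0.0243). Median scaling moved the median of all genes by -0.16 and gave 402 genes higher and 1275 lower, and under it the calls of EGFR, ABCC2 and DNA replication ended (adjusted p of 0.117, 0.340 and 0.0737). The matrix list had an adjusted p of 0.146 without S replicate 3 and 0.111 without TCR replicate 2. It had 0.0547 with no background correction, 0.0548 with the deposited normalized values, 0.0549 at a detection p under 0.01 and 0.0871 with no filter on dim probes. Antigen presentation had 0.0598 and 0.0898 without the same 2 arrays and 0.132 with no filter. Mitosis had 0.0598 without S replicate 3, 0.0510 without TCR replicate 1 and 0.0715 by fry. The calls of ABCC2 (without any S array, TR replicate 1 or 2, or TCR replicate 1 or 2), RND3 (without S replicate 2 or any TCR array), PTTG1 (without TCR replicate 3) and CCNE1 (without TCR replicate 2 or 3) ended with highest adjusted p of 0.113, 0.0828, 0.0543 and 0.0721, and up to 5 lists were called when the same 6 arrays were regrouped across the lines.

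The changes of TR and TCR against S were then set side by side. The genes called in both with the largest shared rise included PTGER2, CST1, HEPH, SLCO2A1 and KRT16P2, with smaller changes of 3.85, 3.84, 2.97, 2.74 and 2.48 on the log2 scale. UBTD1 rose by 2.28 in TR, the keratin KRT16 by 2.45 and 2.22 in TR and TCR, the ribonuclease RNASE1 by 2.42 and 2.18, and LEF1 by 2.09 in TR. KRT20, an intestinal keratin below background in S, was at least 3.44-fold and 4.23-fold higher. On the other side SGPP2, IGFBP2, KCNS3, PGM1, TCEA3, ANXA13 and SLC46A3 fell in both lines, TPPP3 fell by 2.86 in TCR, CYB5R2, detected on 2 of 3 TR arrays, fell by 2.88 in TR, and PTGFRN, a membrane partner of tetraspanins, was at least 4.79-fold and 4.53-fold lower. In all 692 genes rose and 618 fell in both lines, where independent lists of the same sizes would share 106.4 and 90.5, and 139 and 133 changed at least 2-fold in both. The counts in both lines were 320 and 775 with median scaling, 1064 and 965 with array weights, and 323 and 287 at an adjusted p under 0.01.

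Across 10757 genes, which are not independent replicates, the TR and TCR changes correlated at r = 0.833, and 79.6% of genes had the same sign. Unchanged groups simulated against shared controls gave a mean r of 0.5002 (highest of 100 simulations 0.519), 66.7% with the same sign and 0 genes called in both. The covariance was 0.186 against a simulated 0.0147, a difference of 0.171. The simulation gave the 3 groups the same spread for each gene. The S arrays were more spread, with a lowest r within the group of 0.975 against 0.991 in TR and 0.989 in TCR. More spread in the shared controls raises the r without effect, so the simulated values may be too low. The 3 S arrays cannot be split into parts of at least 2, so part of the excess may come from the shared controls.

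**Figure D3:**
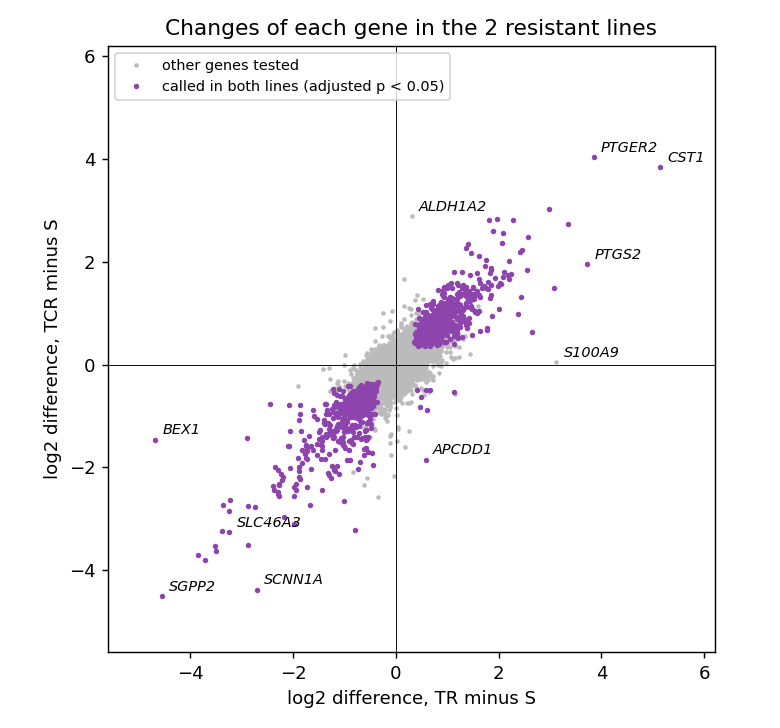
Log2 difference of TR minus S (x axis) against TCR minus S (y axis) for each of 10757 genes, with genes called in both comparisons in purple. Most called genes lie along the diagonal (r = 0.833, simulated without effect and with equal spread in the groups 0.5002), and APCDD1, S100A9, ALDH1A2 and BEX1 lie away from it.

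The comparison of TCR with TR tested the difference between the resistant lines directly. PTGS2 was lower in TCR by 1.78 ± 0.29 on the log2 scale (a difference of -1.78, SE, n = 3 arrays per group, adjusted p = 0.00964), and SLC46A3 differed by -0.03 (adjusted p = 0.959). S100A9, below background in TCR, was at least 5.68-fold lower (adjusted p = 6.41e-07). ALDH1A2 was higher in TCR by 2.57 ± 0.13 (SE, adjusted p = 3.95e-06), and the probe used for BEX1 was higher by 3.22 (adjusted p = 0.000116), with 0.20 for its other kept probe. ERBB2 differed by 0.06 (adjusted p = 0.851, other probe -0.00), EGFR by -0.10 (adjusted p = 0.815) and TUBB3 by -0.57 (adjusted p = 0.0556).

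FES, a cytoplasmic tyrosine kinase, rose by 1.68 from TR to TCR, REG1A, a secreted gut protein detected on 2 of 3 TR arrays, by 1.51, and the phospholipid transfer protein PLTP, below background in TR, was at least 2.02-fold higher. ACTL8, below background in TCR, was at least 4.49-fold lower. The Wnt inhibitor APCDD1 fell by 2.43, the receptor phosphatase PTPRM by 2.22 (detected on 2 of 3 TCR arrays) and TP53I13 by 2.14. Of 17 inflammatory genes 0 rose and 0 fell, and 0 rose and 2 fell adjusted over the list alone, while the list moved down (list adjusted p = 0.00688, and adjusted p = 0.211 with an estimated correlation), with 1 up and 7 down at an unadjusted p under 0.05 and LCN2 at -0.93 (adjusted p = 0.109). Lists of matrix, lysosome and mitosis moved down and the gut list moved up, all with an adjusted p of 0.0425. With an estimated correlation their adjusted p was 0.703 for the first 3 and 0.292 for the gut list. Of 26 matrix genes 0 rose and 1 fell (TIMP2, a metalloproteinase inhibitor, by 0.91), and 1 rose and 7 fell adjusted over the list alone. Of 41 lysosome genes 0 rose and 1 fell, and 0 rose and 3 fell adjusted over the list alone, with the protease gene CTSL down by 0.72. Of 30 mitosis genes 0 rose and 1 fell, also adjusted over the list alone, with the kinetochore gene CENPF down by 0.61. Of 27 gut genes 2 rose and 0 fell, also adjusted over the list alone. At an unadjusted p under 0.05 limma gave 2 up and 9 down for matrix, 0 and 9 for lysosome, 0 and 3 for mitosis, and 9 and 2 for the gut list. The other lists reported here had adjusted p from 0.508 to 0.989. Among these the median and the mean differed in sign for interferon (0.01 and -0.02), NRF2 (0.03 and -0.09) and squamous genes (0.08 and -0.24). Camera pointed up against both for ABC transporters (-0.05 and -0.03), microtubule-associated genes (-0.0048 and -0.0045) and junctions (-0.06 and -0.01).

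In all, limma called 49 genes higher and 150 lower in TCR than in TR, of which 14 and 49 changed at least 2-fold. Of these 199 genes, 129 were called in TR against S, 142 in TCR against S and 10 in neither. Runs of neighbouring genes described below held 27 of the 199, so the changes of such neighbours may not be separate. Among the genes that moved the same way in both lines, 24 that rose and 50 that fell also differed between the lines. The counts were 24 and 145 with median scaling, 135 and 272 without S replicate 1, 20 and 72 without TR replicate 1, 14 and 59 without TR replicate 2, 17 and 75 without TCR replicate 2, 21 and 77 without TCR replicate 3, with 24 higher genes without TR replicate 3, and PTGS2 was no longer called without TR replicate 1 or 2 (highest adjusted p 0.0559). The matrix, lysosome, mitosis and gut lists each lost their call without S replicate 3 (adjusted p = 0.0556) and in a fit on the 2 groups compared (0.0527). Further losses came for matrix without TR replicate 1 or 3 or TCR replicate 1 or 3 (highest adjusted p 0.191) and for lysosome without any TR array or TCR replicate 1 or 3 (0.520). They also came for mitosis without TR replicate 3 or TCR replicate 1 or 2 (0.656) and for gut without TR replicate 3 or any TCR array (0.187). With no filter on dim probes the adjusted p was 0.347 for matrix, 0.269 for gut and 0.0991 for the inflammatory list. Median scaling gave 0.109 for lysosome and 0.0526 for mitosis. Lysosome had 0.0511 with the replicate block and 0.114 by fry, mitosis 0.127 with array weights and 0.306 by fry. Gut had 0.0508 with array weights and 0.0547 with the mean of a gene's probes. The genes CTSL and CENPF lost their calls in several fits (highest adjusted p 0.141 and 0.188), and up to 2 lists were called when the same 6 arrays were regrouped.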

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

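The tests of mixing and of RNA quality for S replicate 1 were chosen only after the result was seen, and the genes that moved in opposite directions in the lines were picked after their values were seen; the comparison of TCR with TR, the splits and the markers of other cell types were chosen earlier.

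The effects of the 2 resistant lines against S differed, by the direct test between TCR and TR, for 199 genes. Those below are the genes that passed it among the ones taken by the naming rule or called in opposite directions in the lines. Genes that lie in the same run of neighbours, described later, may not be separate differences. On the log2 scale BEX1 was higher in TCR by 3.22 (0.20 by its other kept probe), ALDH1A2 by 2.57, FES by 1.68, REG1A by 1.51, FKBP10 by 0.99, CXADR by 0.87 and CLDN18 by 0.66. The TCR minus TR difference was -2.43 for APCDD1, -2.22 for PTPRM, -2.14 for TP53I13, -1.78 for PTGS2, -1.67 for SCNN1A, -1.67 for SPIRE1 and -1.59 for PGC. It was -1.29 for OSR1, -1.26 for VLDLR, -1.23 for IFITM2, -1.14 for CGNL1, -1.12 for GSTM2, -1.09 for FNBP1, -1.07 for ABCA3 and -0.998 for MED24. It was -0.91 for TIMP2, -0.88 for GSTM1, -0.72 for CTSL, -0.72 for FGFBP1, -0.62 for SLCO2A1, -0.61 for CENPF and -0.58 for BNIP3. Below background on all arrays of 1 line, so that only a bound holds, S100A9 was at least 5.68-fold lower in TCR, ACTL8 at least 4.49-fold, HOPX at least 3.53-fold and RND1 at least 2.08-fold, and PLTP was at least 2.02-fold higher in TCR. The lists of matrix, lysosome, mitosis and gut genes differed with an adjusted p of 0.0425 each, and the inflammatory list with 0.00688. None of these 5 list calls held with an estimated correlation.

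Probes with no single gene symbol were outside the gene comparisons. Of 4348 such probes, 89 changed at least 2-fold in TR against S, 82 in TCR against S and 11 between TCR and TR, with log2 differences up to 3.03 in TR and down to -3.11 in TCR.

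The 6 arrays of a comparison can be split into groups of 3 in 10 ways, so the smallest share is 0.1 and a share under 0.05 cannot be reached. In each comparison 1 of the 10 splits, the real one, gave a count as large, for genes, for 2-fold genes and for lists. The real splits gave 2320, 1826 and 199 genes for TR minus S, TCR minus S and TCR minus TR, of which 428, 413 and 63 changed at least 2-fold. The highest other split gave 0 genes with limma in each comparison, and 592, 840 and 766 genes at an unadjusted p under 0.05, where the real splits gave 3884, 3219 and 1555. For lists the real splits gave 10, 9 and 5 calls and the highest other 7, 5 and 2. Every other split has arrays of both lines in each group, so it keeps part of the line difference and widens the spread within groups. Its list calls therefore do not measure how often camera calls an unchanged list. Likewise its 0 genes do not measure what chance would give.

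S replicate 1 stood apart from the other S arrays, with r of 0.975 and 0.978 against 0.993 between those. Fibroblasts and leukocytes in it are argued against: 1 of 29 fibroblast and leukocyte markers with a named probe was detected on S replicate 1 and on neither other S array, and 2 on S replicate 2 alone. These markers cannot show cells of any other type, which stay open as untested for S replicate 1. RNA quality may have a part, since its difference from S replicate 3 followed gene span with a rank correlation of 0.183 in size, against at most 0.0870 between arrays of a group without it, though span is only a proxy for quality. RNA of a resistant line mixed into it is argued against as the whole reason, since a mixture would lie nearer to the resistant arrays and its highest r with one was 0.958, against 0.969 to 0.974 for the other S arrays. A mixed-in part beside another cause cannot be told apart, because the slope of its deviation on the line's change was 0.0809 in 1 of 4 fits and -0.0745 in another, with 0.0020 and -0.00062 in the rest, and a difference between cultures stays open as untested.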

How the results depend on the processing

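All alternatives were planned except the lists without genes of shifted neighbourhoods, which were chosen after seeing the data and gave 10, 9 and 5 list calls, as many as with those genes. Without them 2 of 12 tubulins rose and 1 fell in each line, against 3 and 2 of 14 with them. Of 23 apoptosis genes 3 rose and 3 fell in TR, against 6 and 3 of 26. In TCR 2 rose and 1 fell, against 5 and 1. Changes of the members left out cannot be told apart from a shift of their neighbourhood. Of 78 called values of fixed and ranked genes, 71 stayed called under every one of 22 settings, 7 lost the call in at least 1 and 0 reversed. The ranked genes were picked for large changes in these data, so this does not measure the calls in general. With 1 array left out, as few as 1392 of 2320 calls were kept in TR (without TR replicate 1). The lowest numbers were 1208 of 1826 in TCR (without TCR replicate 2) and 72 of 199 between the lines (without TR replicate 2). Of 182 called values of list members, 122 stayed called, 60 lost the call in at least 1 setting and 0 reversed. The cause of a lost call was not tested except where fewer arrays or a stricter threshold entered by construction. Signal over background limits genes whose probe was detected on no array of a group, and their folds are bounds.

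Median scaling left 670 genes up in TR, 402 up in TCR (2-fold 115 up and 340 down), 24 up between TCR and TR, 320 up in both and 3 lists between TCR and TR. It moved the median of all genes by -0.093 in TR minus S, -0.16 in TCR minus S and -0.066 in TCR minus TR. The share of calls that were up became 36.7%, 24.0% and 14.2%, against 53.9%, 50.2% and 24.6% with quantile normalization. Array weights gave 1967 up and 1814 down in TR, 150 and 314 between TCR and TR, 1064 and 965 in both, and 3 lists between TCR and TR. An adjusted p under 0.01 gave 602 and 486 in TR, 438 and 437 in TCR, 15 and 60 between TCR and TR, 323 and 287 in both, with 5 lists in TR and 1 between the lines. The 2-fold counts up and down in TR, TCR and TCR minus TR were 85 and 44, 71 and 65, 3 and 11 without background correction, 85 and 44, 71 and 65, 3 and 10 with the deposited normalized values, and 143 and 106, 116 and 131, 7 and 28 with an offset of 50. A fit on the 2 groups compared gave 1964 calls in TR minus S and 1285 in TCR minus S, against 2320 and 1826 in the joint fit. Between TCR and TR it gave 263 calls against 199, with 80 genes up and 1 list. No filter on dim probes left 2 lists there. An estimated correlation left 1, 0 and 0 lists, and fry called 16 in TR and 17 in TCR.

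Leaving out 1 array at a time gave 777 to 1249 genes up and 661 to 1056 down in TR (2-fold 214 to 282 and 178 to 210), 654 to 1003 and 613 to 978 in TCR (2-fold 179 to 221 and 224 to 256), and 14 to 135 and 59 to 272 between TCR and TR (2-fold 11 to 17 and 40 to 56). It gave 515 to 724 up and 447 to 610 down in both, r from 0.802 to 0.854, and 7 to 10, 6 to 11 and 1 to 5 lists. The lowest list counts came without TR replicate 1 for TR, without S replicate 3 for TCR, and without S replicate 3, TR replicate 3 or TCR replicate 1 between the lines.

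The replicate numbers did not pair the samples, since same-number correlations of deviations ran from -0.082 to 0.29, though 6 of 9 arrays correlated best with their own number, a hint from the data and not the design. With the replicate number as a block the counts were 1275 and 1095 in TR, 918 and 902 in TCR, and 37 and 147 between TCR and TR, 701 and 629 in both, with 10, 9 and 4 lists. Of the calls without the block, 2163 of 2320, 1671 of 1826 and 157 of 199 were shared with it. A slide block was not run because no slide is named in the sources used here.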

Other observations

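All tests on runs of neighbouring genes were chosen only after the result was seen; the 8 genes below were also chosen after their values were seen.

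Among genes called in both lines, 8 moved in opposite directions against S. APCDD1, a Wnt inhibitor, rose by 0.58 in TR and fell by 1.85 in TCR, and SPIRE1, an actin nucleator, rose by 1.13 and fell by 0.54. RND1 rose by 0.61 in TR and, below background in TCR, was at least 1.36-fold lower there, OSR1 rose by 0.46 and fell by 0.83, and the junction gene CGNL1 rose by 0.66 and fell by 0.49. FNBP1, a membrane-bending protein detected on 2 of 3 TCR arrays, rose by 0.59 and fell by 0.50, the glutathione transferase GSTM2 rose by 0.49 and fell by 0.63, and TIMP2 rose by 0.41 and fell by 0.50. The adjusted p of these values was at most 0.0430. Those that lie in a run of neighbouring genes, described next, may not have moved separately.

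Neighbouring genes moved together along the gene order of GRCh38.p14. From SS18 to PARD6G, 56 of 88 genes rose and 1 fell in TR (median log2 0.63), and from RMC1 to PARD6G 66 of 94 rose and 2 fell in TCR (median 0.77). Just before that run in the gene order, 26 of 45 genes from METTL4 to SNRPD1 fell in TCR and 1 rose (median -0.92), and 21 of 35 from ZBTB14 to SNRPD1 fell in TR and 3 rose (median -0.55). From NOC2L to FBXO6, 40 of 87 genes fell in TR and 1 rose, from WASH7P to TNFRSF1B 45 of 97 fell in TCR and 0 rose, and from NRIP1 to BACE2 29 of 63 rose in TCR and 0 fell. Between the lines, 20 of 47 genes from NDC80 to GATA6 were lower in TCR. In all 15, 16 and 5 runs were found for TR minus S, TCR minus S and TCR minus TR, and they held 5.88%, 7.45% and 1.24% of the genes tested and 13.5%, 20.2% and 13.6% of the genes called.

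A chance order of the genes is argued against for the strongest window of each comparison, with a permutation p of 0.001, the smallest that 1000 permutations can give. That p does not cover the weaker runs. Window means used each gene's difference from the median of the placed genes, limited to 1 in size. The strongest permuted window had a mean of 0.477, 0.465 and 0.334 in size for TR minus S, TCR minus S and TCR minus TR. Between TCR and TR only the run from NDC80 to GATA6 (-0.81) lay beyond it, and the highest upward window was 0.295. Several runs in TR and in TCR also stayed within the strongest permuted window. Among them the run from KMT2B to ZNF585A reached -0.41 in TR, and that from NIPAL3 to HMGN2 reached -0.39 in TCR. In the 8 runs with at least 20 other probes of their genes, single faulty probes are argued against because 75% to 97.0% of those lay on the run's side of the median of the remaining such probes, while the tests leave this open for 28 runs, with at least 75% in 18 and the lowest share at 58.3% of 12 probes from UBN2 to ARHGEF35. Normalization between arrays is argued against because it added at most 17.2% of a run's shift against all other genes, from NDC80 to GATA6 (-0.46 with it and -0.38 without), with bootstrap upper limits over a run's genes of at most 43.9%. A DNA copy-number difference between the lines is a candidate explanation for the strongest upward run in TCR: a run found on every second gene, from POTEC to ADNP2, held for 94.1% of the 51 genes in between in TCR minus S, where 50.5% of all genes went that way. Other regional causes predict the same and no DNA was measured, and a run found the same way between TCR and TR, from THOC1 to TRAPPC8, held for 54.3% of its 35 genes in between (at least 75% in 13 of the 20 other runs), so this stays a hypothesis.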
